A study of Mus musculus with 16 samples.

How the data were processed

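Genomic DNA from tails of 8 mice of 1 family was hybridised with DNA of 1 reference male to a 2-colour oligonucleotide array with tiled probes, each animal in both dye orientations. Per the labels, one channel of each array held the animal and the other the reference, which sets the direction of every ratio. Per the file headers, the arrays were extracted with Agilent Feature Extraction 12.1.0.3 on mm9 positions, and the deposited processed signals are intensities after background subtraction and linear dye normalization. Per the labels, DNA was labelled by version 4.0.8 of the Agilent protocol. The authors' deposited value table holds log2 ratios: each column was set against the scanner values and correlated with an absolute r between 0.97 and 1, with the direction of reference over animal. The column medians ran from -0.00204 to 0.0127, and what further correction the authors applied to most columns stays unknown. The deposited log10 ratio of Cy5 over Cy3 served only to find this relation.

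For each array, log2 of the Cy5 over the Cy3 processed signal was turned to animal over reference. Control spots and spots with an outlier flag were left out (88 to 210 flagged spots per array). Spots of 1 probe were averaged, and each array was centred on its median over autosomal probes. Both orientations of an animal were averaged to 1 profile. Runs of autosomal probes with gaps of at most 10 kb and at least 5 probes formed tiled blocks. A circular binary segmentation written for this purpose split each block where the circular t reached 5 against a noise SD from successive differences. A segment was called at 5 or more probes, an absolute mean log2 of 0.25 or more, and 0.15 or more in the same direction in each orientation. Segments of different animals that shared probes were merged into regions, and an animal was a carrier where its calls covered at least 50% of a region. Call borders can differ between animals with the same values, which the alternative with carriers set by the regional mean addresses.

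Progeny segments not covered by a parent were compared with the nearer parent against 10000 random windows of as many probes, two-sided, with Benjamini-Hochberg adjustment over the segments. They were kept where the nearer parent was under 50% of the progeny value. These p-values served only as a filter: the segments were selected for a gap between progeny and parents while the windows were not, and windows along the genome give no spread between animals. Transmission was tested with an exact binomial test, and counts of segments with an exact permutation test. Block means were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The other steps ran in Python with the versions recorded beside the results.

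The segmentation was tested on simulated data, with 200 segments added to the scaled difference between the dye orientations of the male parent over 120662 probes, without the requirement on each orientation. Of segments of 5 probes, 100% were recovered at an added log2 of 0.58 and 90.5% at 0.3, with 0 calls elsewhere. The noise SD of that profile was 0.0524, while the profile of progeny 5 had 0.0768, so recovery there was not tested. For progeny against parents, limma on 1635 simulated blocks with 200 changed recovered 92.5% at a change of 0.1 with 12 false calls. For progeny against the reference it recovered 49.5% at 0.25, which is its own threshold, and 100% at 0.58. The recovery of 92.5% applies to a change between the means of progeny and parents. Recovery of a change in only part of the progeny was not tested.

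The 16 arrays lay on 4 slides of 4 arrays, 2 animals to a slide, and were scanned on 2 days. Slide 1 held both parents, and slides 2, 3 and 4 held progeny 1 and 2, 3 and 4, and 5 and 6. The parents and progeny 1 and 2 shared a scan day. Slide was therefore fitted as a random block, and scan day as a fixed block. For progeny against parents, the fit with slide gave a correlation of 0.46 within slides, and no progeny shared the slide of the parents. The recovery on simulated blocks is therefore not taken as the power of the real comparison.

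Regions were named by a rule set before the data were examined: all or up to 10 regions of each class, ranked by absolute mean log2 times the square root of the number of probes, and the 5 highest and 5 lowest blocks past the threshold of each limma comparison. Regions named outside the rule are marked as chosen after their values were seen. The files used here pair no gene names with probes, and the gene table at hand is of another genome build, so positions are given in mm9 without genes and the gene lists set beforehand were not used here.

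Alternatives planned beforehand were normexp background correction with an offset of 50, loess, a filter on dim probes, the authors' value table, 1 dye orientation at a time, other thresholds, numbers of probes, split values, gaps and overlaps, block medians, leaving out each animal, and slide as a block. Normexp used median signals, since the files hold no mean signals. Removal of a trend with probe length, carriers by regional mean, joined regions, leaving out progeny 5 or progeny 5 and 6 from the calls, and scan day were added after the data were seen.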

Results

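Copy number was measured by array comparative genomic hybridization in tail DNA of 1 family of C57BL/6JNrs mice, an inbred strain: 1 male parent, 1 female parent and their 6 progeny. In this assay, DNA of an animal and DNA of a reference compete for the same probes, so that a log2 ratio above 0 marks more copies in the animal. Every animal was hybridised 2 times against the same reference male of the colony (mouse 14), once with the animal in Cy5 and once in Cy3, which gave 16 arrays for 8 animals. The 2 arrays of an animal were averaged and counted as 1 replicate. The series title describes males exposed to 0.05 mGy per day of gamma rays for 400 days, while the design text calls the male of this family non-irradiated. The labels therefore conflict on the exposure of the male parent, and no other family was analysed here, so that no comparison by irradiation could be made. Each array held 128740 non-control spots for 124702 different probes, of which 120662 autosomal probes fell in 1635 tiled blocks with a median of 76 probes. These blocks are the surroundings of probes picked in an earlier genome-wide screen, so counts of segments describe chosen regions and not the whole genome. Green signal-to-noise ranged from 145 to 250 and red from 121 to 246 over the arrays. The number of arrays limits the precision.

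Signed values are log2 of animal over reference, which is opposite to the direction of the authors' deposited value table. The 48 X probes showed the direction: their mean was 0.92 ± 0.09 (SD over probes) in the female parent and 0.00 ± 0.05 in the male parent.

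The first comparison asked which segments of each animal differ from the reference. In all, 260 segments were called over the 8 animals, and they merged into 168 regions. The male parent had 17 segments, the female parent 16, and progeny 1, 2, 3 and 4 had 11, 29, 9 and 13. Progeny 5 stood apart with 145 segments, of which 133 were gains and 134 held fewer than 10 probes, and progeny 6 had 20. The number of segments of 10 or more probes was 14 in the male parent, 22 in progeny 2 and 11 in progeny 5. In the male parent and progeny 2 most of these were parts of 1 gain on chromosome 4, so they do not count separate aberrations. Calling without the requirement on each orientation was applied to the difference between the dye orientations, with each probe's mean over the animals removed. It found 0 segments in every animal, although this does not count errors that both orientations share. In progeny 5 that difference had a noise SD of 0.0456, against 0.0768 in its profile, so the 0 says little about its calls. The total was 115 without progeny 5. The count of progeny 5 depended on the setting, with 239 segments with normexp and 479 at a threshold of 0.15. At a threshold of 0.4 it had 28, fewer than the 47 of progeny 2.

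**Figure D1:**
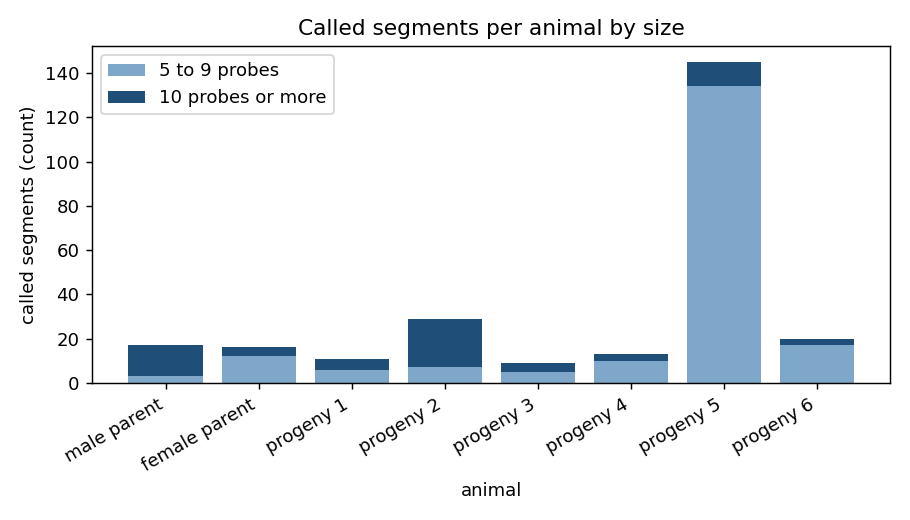
Bars give the number of called segments (y axis, count) in each of the 8 animals (x axis), split into segments of 5 to 9 probes (light) and of 10 probes or more (dark). Progeny 5 reached 145 segments, 134 of them in the light class.

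The second comparison asked which aberrations the whole family shared against the reference. A block on chromosome 14 (mm9, 53750331 to 53764803, 17 probes) was lower than the reference in 8 of 8 animals, with a mean of -0.81 ± 0.04 (SD, n = 6) in the progeny, -0.83 in the male parent and -0.80 in the female parent. A second segment on chromosome 14 (54223715 to 54233855, 7 probes) was lower in all 8 animals, at -0.50 ± 0.05 (SD, n = 6) in the progeny, -0.51 in the male parent and -0.50 in the female parent. These 2 were the regions whose calls covered at least 50% of the probes in every animal, and with any shared probe counted there were 3. A further 5 neighbouring parts of chromosome 14, picked after their values were seen, were lower than the reference in 8 of 8 animals although their calls differed between animals. From 53961688 to 53991911 (28 probes), where every animal had a call but the male parent and progeny 6 had calls on fewer than 50% of the probes, the progeny mean was -0.41 ± 0.01 (SD, n = 6), against -0.42 in both parents. The part from 54264544 to 54279592 (14 probes) varied more, from -0.29 in progeny 3 to -0.53 in progeny 5. Every animal was set against 1 reference mouse, so a shift in all of them cannot be separated from a difference of that mouse. The count of 2 was 7 with carriers set by the regional mean, an alternative added after the data were seen, and 1 with at least 10 probes.

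Over whole tiled blocks, limma found 5 blocks in which the 6 progeny differed from the reference past an adjusted p of 0.05 and a log2 of 0.25, and all 5 were lower and lay on chromosome 14. The strongest was the block from 53750331 to 53764803, with a log2 of -0.81 (SE 0.012, adjusted p = 1.6e-09 by limma), lower in 6 of 6 progeny. The other blocks were 54116332 to 54134574 at -0.50, 54264544 to 54298759 at -0.38, 54215848 to 54233855 at -0.31, and 53961688 to 53992647 at -0.29. The same limma test found 0 blocks higher past the threshold. In either direction 83 blocks had an unadjusted p under 0.05, close to the share of 0.05 that chance alone would give. The spread of the single reference mouse is left out of this test, and with a largest gap of 50 kb within a block 3 blocks passed.

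The third comparison asked how aberrations carried by 1 parent appeared in the progeny. The largest was a gain on chromosome 4 in the male parent and in progeny 2 alone. It ran from 101109394 to 101270967 (916 probes, 161574 bp), with a log2 of 0.54 ± 0.09 (SD over probes) in the male parent and 0.50 ± 0.12 in progeny 2. The female parent stood at 0.00 ± 0.05, and progeny 1, 3, 4, 5 and 6 at -0.01, 0.00, -0.01, 0.02 and 0.01. With the animal in Cy5 the gain was 0.58 in the male parent and 0.54 in progeny 2, and with the animal in Cy3 it was 0.50 and 0.47. The gain ended sharply at both sides: the 20 probes before it averaged 0.00 in the male parent and in progeny 2, and the 20 probes after it averaged 0.00 and -0.02. The segmentation broke this gain into 10 called regions, and the whole span was joined after their values were seen. The joined span also holds stretches outside the calls, the longest from 101148430 to 101173664, so a gain without breaks was not shown. Of the 10 regions of 1 parent ranked first by the rule, 8 were such parts of the gain, with male parent values from 0.53 to 0.57 and progeny 2 values from 0.48 to 0.58.

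**Figure D2:**
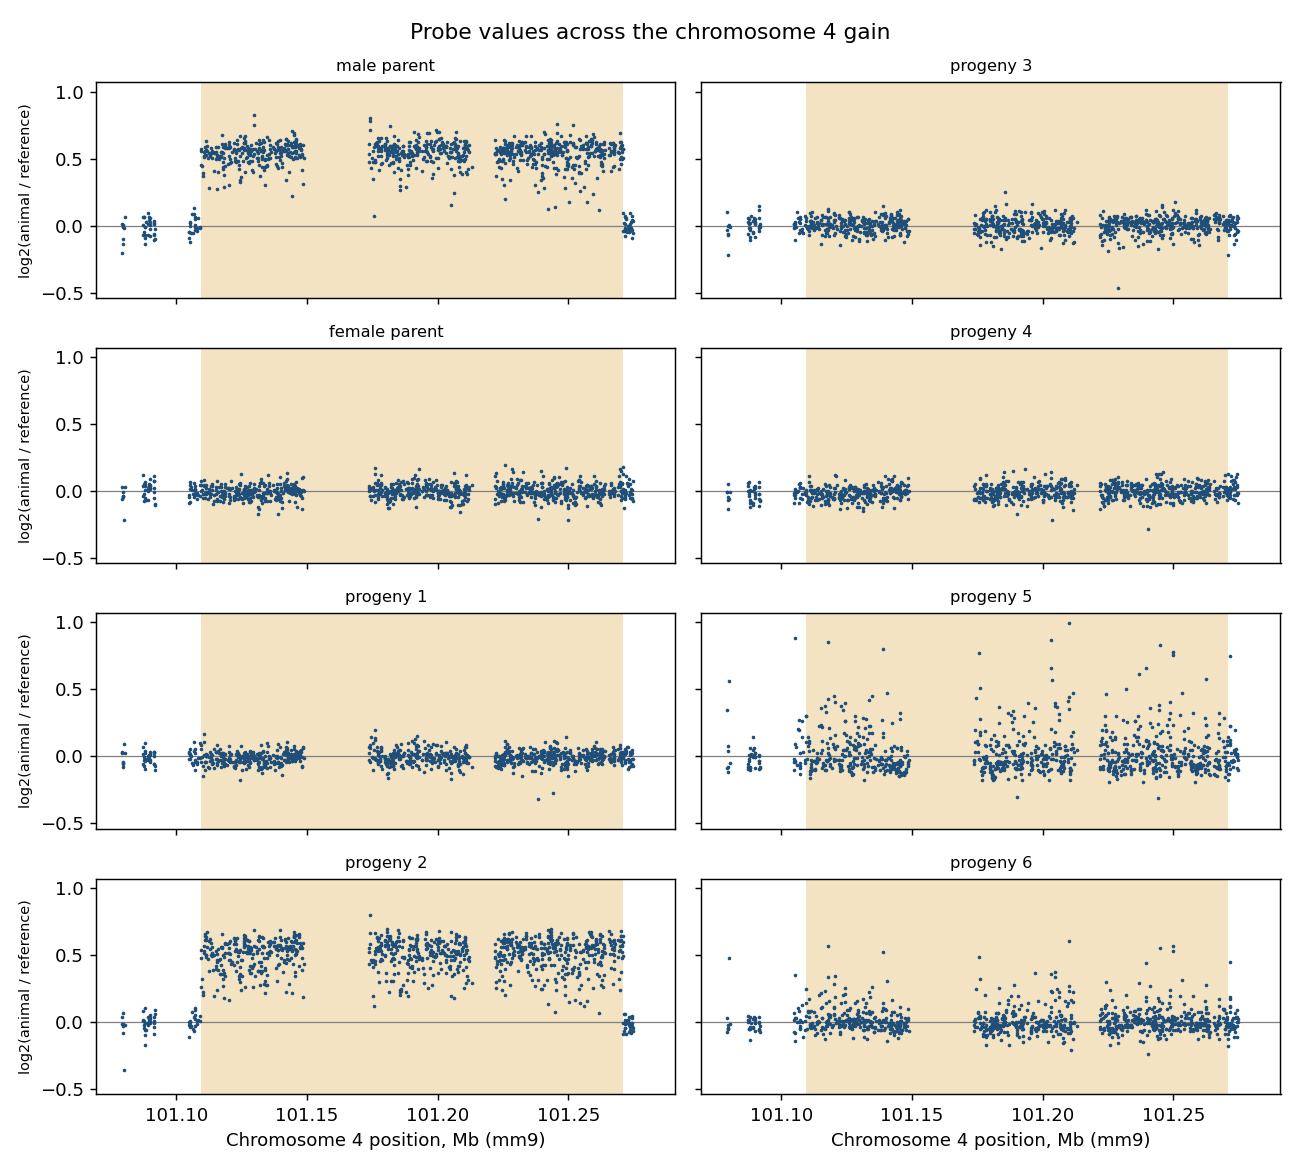
Each panel shows 1 animal, with every point a probe placed by chromosome 4 position in Mb (mm9, x axis) and its log2 of animal over reference averaged over both dye orientations (y axis), and the shaded span from 101109394 to 101270967. The male parent and progeny 2 sit near 0.54 and 0.50 inside the span, and the other 6 animals near 0.

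A loss on chromosome 13 (101050371 to 101091511, 32 probes) was carried by the female parent at -0.64 ± 0.22 (SD over probes) and by 4 of the 6 progeny. Progeny 1, 2, 3 and 5 stood at -0.56, -0.58, -0.68 and -0.63, whereas the male parent, progeny 4 and progeny 6 stood at -0.02, 0.02 and -0.03. A loss on chromosome 3 (25432440 to 25444229, 7 probes) was carried by the female parent at -1.19 ± 0.63 (SD over probes) and by progeny 5 and 6 at -1.37 and -1.39, with the other 5 animals between 0.00 and 0.02. The X probes of the same 3 animals had medians of 0.94, 0.93 and 0.94, and those of the other 5 lay between -0.01 and 0.02.

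In all, calls covered at least 50% of 23 regions in exactly 1 parent, and with any shared probe counted there were 22 such regions. The number of progeny that met the same rule was 1 for 13 regions, 2 for 7, 4 for 1 and 5 for 2. An exact binomial test against a share of 0.5 left 0 of the 23 past the adjusted threshold, with an exact two-sided p of 0.219 for the gain on chromosome 4 and 0.688 for the losses on chromosomes 13 and 3. With 6 progeny the smallest exact p is 0.0313, and it is the only one under 0.05. No region could therefore have passed alone after adjustment over 23 regions: most of them would have had to share that p. The count of 0 says nothing about a share of 0.5. With the animal in Cy3 only, 40 of 63 regions passed, all of them tied at that smallest p, and none would have passed without the others. These calls lack the check by the other orientation, and the female parent had 55 of them against 16 in the main setting. The 40 are therefore not taken as a departure from a share of 0.5. Parts of 1 gain were tested as separate regions, and 4 of the 23 were parts of the chromosome 14 interval, where the values of both parents lay between -0.33 and -0.49. Counted as joined loci with carriers set by the regional mean, there were 11 loci.

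**Figure D3:**
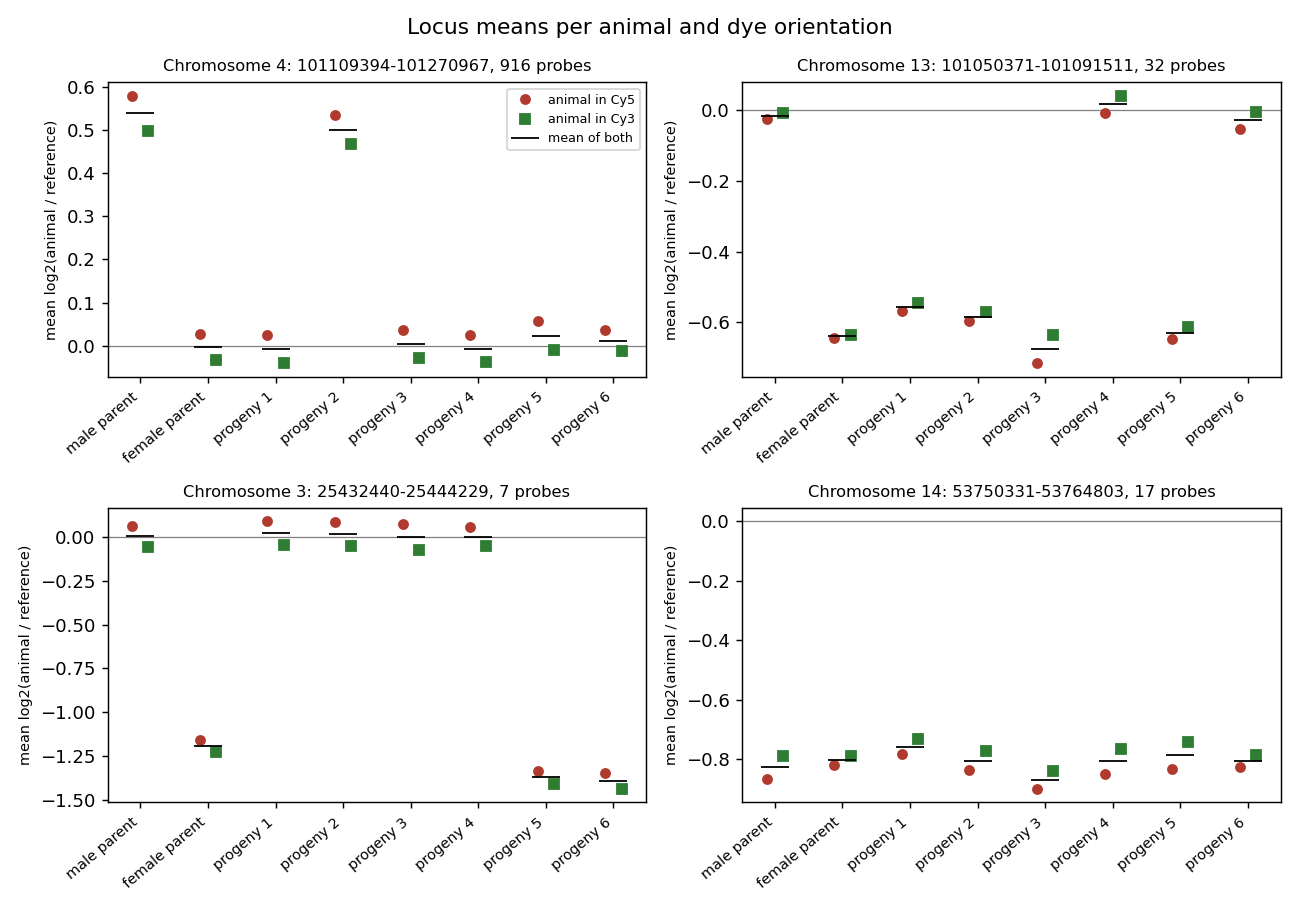
Each panel shows 1 locus, with the 8 animals on the x axis and the mean log2 of animal over reference over the probes of the locus on the y axis; circles are arrays with the animal in Cy5, squares arrays with the animal in Cy3, and lines the mean of both. The chromosome 4 gain is in the male parent and progeny 2, the chromosome 13 loss in the female parent and 4 progeny, the chromosome 3 loss in the female parent and progeny 5 and 6, and the chromosome 14 loss near -0.81 in every animal.

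The fourth comparison asked whether progeny carried segments that neither parent had. Under the rule used to keep such segments, 0 were kept in progeny 1, 2, 3 and 4. Of 151 candidates, 132 were kept, 118 in progeny 5 and 14 in progeny 6, and 131 of the 132 were gains. Their adjusted random-window p-values ran only from 0.0302 to 0.0494, close under the filter's limit of 0.05, so many segments can enter or leave the count together. The kept segments are therefore not a stable count. The kept segments were short, with a median of 5 probes and a range of 5 to 13. The highest was on chromosome 17 (41424141 to 41424376, 5 probes), with 1.11 in progeny 5 against -0.06 in the male parent, and progeny 6 stood at 0.78 there. On chromosome 10 (39251391 to 39251725, 5 probes) progeny 5 had 0.87 and progeny 6 0.56, and both were kept. Further gains of progeny 5 were 0.64 on chromosome 2 (34559866 to 34560404), 0.60 on chromosome 4 (49645870 to 49646420), 0.54 on chromosome 6 (83746370 to 83747412) and 0.54 on chromosome 16 (38492886 to 38493250). The others ranked among the first 10 were 0.58 on chromosome 5 (12390705 to 12390937), 0.57 on chromosome 2 (68058529 to 68059068) and 0.57 on chromosome 11 (64045083 to 64045723). Progeny 5 and 6 shared 1 slide, which held no other animal, and they were the only progeny with the X signal of the female parent. The candidates were picked because the progeny was called and the parents were not, and 1 animal was set against 1 animal, so the random-window p-values that entered the rule are no test of a difference between animals. The count fell to 4 with the animal in Cy3 only, to 2 at a threshold of 0.15 and to 0 with at least 10 probes, and rose to 824 with at least 3. With the animal in Cy5 only it was 179. All calls of progeny 5 rose from 145 to 351 in Cy3 only and to 479 at 0.15, so the kept count did not fall there for want of calls. The kept count was 14 without progeny 5 and 0 without progeny 5 and 6.

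**Figure D4:**
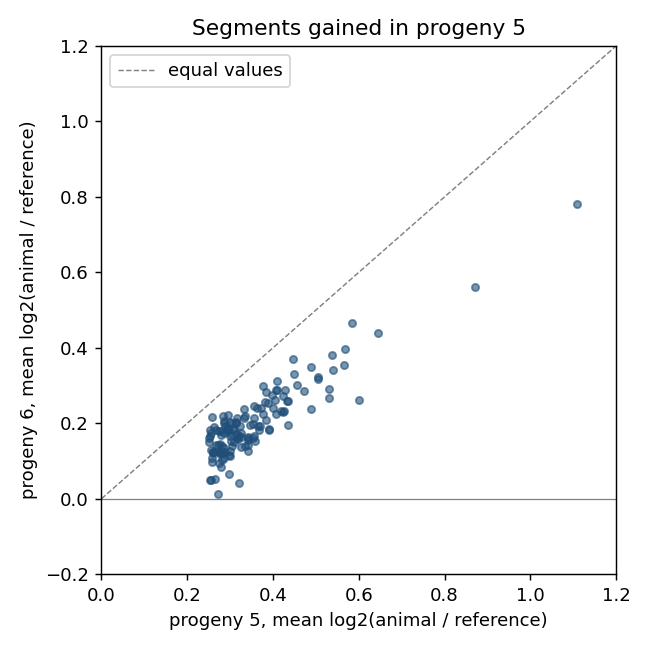
Each point is a segment called as a gain in progeny 5, with its mean log2 of animal over reference in progeny 5 on the x axis and in progeny 6 on the y axis; the dashed line marks equal values. Over the 133 gains the median was 0.32 in progeny 5 and 0.19 in progeny 6.

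The last comparisons set the progeny against their parents as groups. Progeny had a mean of 37.8 ± 53 called segments (SD, n = 6) and the parents a mean of 16.5 (n = 2). The difference of 21.3 had an exact permutation p of 0.714 (two-sided, 28 splits, smallest possible 0.0357), and without progeny 5 it was -0.1. Over the tiled blocks, limma found 0 of 1635 blocks that differed between progeny and parents after adjustment (smallest adjusted p 0.94). Only 8 blocks had an unadjusted p under 0.05, far fewer than the share of 0.05 that chance alone would give. The p-values of this test may therefore be too large, so the count of 0 is weak evidence for group means too. The largest difference in any block was 0.17. This test compares group means over whole blocks. A change in a single animal, or one shared by a parent and part of the progeny, is averaged down in it. The counts of 0 blocks, here and in the fits below, therefore say nothing about such changes. Parents and progeny lay on different slides, and the count was 0 too with slide as a random block, with scan day as a fixed block, and for progeny 1 and 2 against the parents within the scan day that held both groups. In these 3 limma fits 0, 0 and 11 blocks had an unadjusted p under 0.05, again far fewer than that share.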

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

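All tests of explanations in this part were chosen only after the results were seen. Of 40 sets of values over the 6 progeny, 12 had an animal far from the other 5, where chance marks about 1 set in 20 if the sets are not chosen by their values. That rate does not apply to the 11 of the 12 that belong to the chromosome 4 gain, since that gain was picked for its call in progeny 2.

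Progeny 5 had 145 called segments, far above the other progeny, and most were short gains. Over the 133 gains called in it, progeny 6 had a median log2 of 0.19 where progeny 5 had 0.32, with r = 0.897 across segments, which argues against copy gains private to progeny 5. Loess on intensity left 158 calls in progeny 5 and removal of a trend with probe length left 141, so neither trend was the whole source. Progeny 5 and 6 shared slide 4, and their profiles had r = 0.846 across probes, which are not independent replicates. The highest r between the animals of another slide was 0.167. Progeny 5 and 6 were the only progeny with the X signal of the female parent, so sex goes with slide 4 among the progeny. The female parent, on slide 1, had a median of -0.03 over these gains, but 1 animal on another slide does not settle an effect of sex. An effect of slide 4 alone, of sex, of DNA quality or of base composition stays open and cannot be told apart from the animals.

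At the chromosome 4 gain, progeny 2 stood far from its siblings, at 0.50 over the joined span. Its values in the called parts were 0.49, 0.51, 0.50, 0.52, 0.55, 0.48, 0.58, 0.53, 0.46 and 0.50, in the order of their rank with the 2 parts outside the rule last. The male parent carried the same gain.

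The X probes entered no segment call and no block test. Above they gave the direction and were set beside the chromosome 3 loss, and here they serve as a scale for copy number. They had median log2 values of 0.93 in progeny 5 and 0.94 in progeny 6, against 0.94 in the female parent and 0.00 in the male parent. The 3 Y probes had a mean of -3.66 ± 2.78 (SD over probes) in the female parent, -3.14 ± 2.57 in progeny 5 and -2.92 ± 2.47 in progeny 6, and between -0.02 and 0.05 in the other 5 animals. The loss on chromosome 3 went with this X signal in 8 of 8 animals. That match fits a copy of the sequence on the Y chromosome, a candidate explanation found from these same values. The match did not cover the depth. With 1 Y copy beside 2 autosomal copies the loss would read -0.55, against -1.19 in the female parent and -1.37 and -1.39 in progeny 5 and 6. The depth argues against those copy numbers and leaves others open. The last probe had -0.02 in the female parent but -0.36 and -0.39 in these progeny. Loss of 1 of 2 autosomal copies is argued against, since 5 of the 7 probes lay below the single-copy value of -0.94 by more than 2 noise SD in both progeny. Loss of the only copy, with 1 copy in the reference and in the male parent, stays open: the chance that all 6 progeny match the X signal is then 0.0156, and no probe sequence was used here to decide it. Such a loss would leave no copy in the female parent and progeny 5 and 6, where the 7 probes ran from -0.02 to -2.16. The Y probes of these animals had medians of -3.95, -3.55 and -3.10. The depth thus bears on this explanation too, but the wide spread over only 3 Y probes leaves it undecided.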

How the results depend on the processing

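Settings named here as added (trend with probe length, carriers by regional mean, joined regions, leaving out progeny 5 or 5 and 6, scan day) were chosen after seeing the data. Of 266 locus values recomputed for 38 loci, 216 moved by less than their spread, 50 moved more and 0 changed direction. Only carriers entered these values, and their calls already required 0.15 or more in the same direction in each orientation. A change of direction was therefore hardly possible with 1 orientation. The loci also overlap, since parts of the chromosome 4 gain and of the chromosome 14 interval were counted beside their joined spans. The cause of the changes below was not tested, except where fewer animals or stricter calling gives it. The total of 260 segments became 601 with the animal in Cy5 only, 696 in Cy3 only, 720 at a threshold of 0.15, 143 at 0.4, 1342 with at least 3 probes, 66 with at least 10, 115 without progeny 5 and 95 without progeny 5 and 6. The 2 shared regions became 4 with the animal in Cy5 only, 4 in Cy3 only, 4 at 0.15, 6 with at least 3 probes, 1 with at least 10, 1 with a gap of 5 kb, 1 with 50 kb, 7 with carriers by regional mean and 4 when joined. The 132 segments absent from the parents became 4 in Cy3 only, 2 at 0.15, 20 at 0.4, 824 with at least 3 probes, 0 with at least 10, 14 without progeny 5 and 0 without progeny 5 and 6. The 23 regions of 1 parent became 46 in Cy5 only, 63 in Cy3 only, 38 with at least 3 probes, 12 with at least 10 and 11 when joined; the 0 past the binomial threshold became 40 in Cy3 only. The difference of 21.3 segments between progeny and parents turned to -1.5 at 0.4, -1 with at least 10 probes, -0.1 without progeny 5 and -1 without progeny 5 and 6, with exact permutation p-values of 0.857, 0.893, 1 and 1. The 5 blocks of progeny against the reference became 3 with a gap of 50 kb, where fewer and longer blocks are tested, and stayed 5 when any progeny was left out. Progeny against parents stayed at 0 blocks in every setting that kept both parents. As a test of group means it does not address changes in single animals. A correction for GC content was not run, since it needs probe sequences. No paired analysis was possible because the labels number no parent to match a progeny and no parent shared a slide with a progeny. Between 130 and 256 spots per array were not well above background in both channels, and the filter on them gave 254 segments.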

Other observations

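All tests in this part were chosen only after the values were seen. Small gains on chromosomes 10, 3, 6, 11 and 17 were called in the female parent with progeny 4, in most cases with progeny 1 too. On chromosome 10 (16582079 to 16583619, 11 probes) the female parent had 0.43, progeny 1 0.35 and progeny 4 0.48, while the male parent had 0.11 and progeny 6 -0.13. On chromosome 17 (51798206 to 51798407, 5 probes) these 3 animals had 0.49, 0.38 and 0.47, while the male parent had 0.13 and progeny 6 had -0.16. The values were graded more than split into carriers and others. On chromosome 10 (25989237 to 25989467, 5 probes) the male parent had 0.22 and progeny 2 0.13, next to 0.54 in the female parent. On the same chromosome (114606521 to 114607308, 7 probes) they had 0.19 and 0.14 next to 0.36. On chromosome 11 (56082315 to 56083296, 5 probes) progeny 1 had 0.25 without a call. The female parent, progeny 1 and progeny 4 lay on 3 different slides.

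The gain on chromosome 4 may be 1 extra copy of a sequence with 2 copies in the reference, which the values left open. Scaled by the X signal of the female parent (0.94), such a change would read 0.55, and the mean of the 2 carriers, 0.52, lay 1.69 standard errors between carriers from it. Without that scaling it would read 0.58, at a distance of 3.46 standard errors, and taken over probes the distances were 9.99 and 20.5 standard errors. The standard error between carriers rests on only 2 animals, and that over probes leaves out the spread between animals.

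The loss on chromosome 13 was set against copy numbers in the same way. Its mean over 5 carriers was -0.62, with a standard error of 0.021 between carriers and 0.034 over probes. Loss of 1 of 2 copies would read -0.94, which is 15.5 and 9.60 standard errors away, so the mean argues against it only if all probes respond alike. They did not: the SD over probes was 0.22 in the female parent and 0.24 in progeny 3, against noise SDs of 0.047 and 0.051. The lowest probes reached -1.02 and -1.07 in these 2 animals. Neither standard error measures probes that respond too weakly in every carrier, so this loss was not excluded. A change from 3 copies to 2 would read -0.55, at 3.13 and 1.94 standard errors, and -0.58 without the scaling, at 1.55 and 0.963 standard errors, so it was neither excluded nor established. The distances over probes and those without scaling were computed after the first distances were known. Probes that also bind a related sequence elsewhere were not tested.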
